A study of Glycine max with 2 samples.

How the data were processed

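Small RNA was sequenced from 2 soybean sources, laser-captured seed coat parenchyma and whole seed, with 1 library each. Per the labels' protocols, the harvested seeds were divided into 2 pools. Seeds for capture were fixed in ethanol and acetic acid, embedded in paraffin and cut into 10 µm sections. Total RNA of the captured tissue was extracted first and small RNA enriched from it, whereas small RNA of the whole seed was enriched directly. Libraries were made from 50 ng of enriched small RNA by adapter ligation and PCR, with 12 and 20 cycles given and the library each belongs to not stated, and were read as single-end 76-base reads. Compartment, fixation, extraction and PCR therefore cannot be separated in these 2 libraries.

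The deposited values are raw counts per distinct sequence, one sequence with its length and count per line, as the files themselves show. The reads had been trimmed to tags of 15 to 24 nt, with 417 counts in seed coat parenchyma and 198 in whole seed under 18 nt. Bowtie is named in the submitters' processing notes, without a version. The genome build for these files and the filters the authors applied are not given in the sources used here. Some sequences are listed on several lines (6652 tags with 2.33% of counts in seed coat parenchyma, and 19884 tags with 4.13% in whole seed), and these counts were summed.

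The tags are not all written in the direction of the RNA. Of 68 detections of a listed mature miRNA, counted per library, 20 were only as the reverse complement and 0 in both directions within a library. Of 30 mature sequences detected in both libraries, 7 were listed in opposite directions. Family matches were therefore made in both directions. The planned shares by first base are not reported, because the listed first base is not always the start of the RNA. No tag of either library held an exact match of 18 nt or more to 3 conserved stretches of ribosomal RNA (555 bases). The floor of 3 counts was 0.424 CPM in seed coat parenchyma and 0.208 CPM in whole seed, and the upper 95% Poisson limits of 0 counts were 0.521 and 0.256 CPM. The stretches were written from general knowledge and not checked against a database, and whether the authors filtered rRNA is not given in the sources used here. Tags that overlap the start of the 5.8S stretch by part of their length were present, at 1.81% and 0.698% of counts.

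CPM values, counts per 1000000, were computed from each library's total counts. Shares have exact Clopper-Pearson intervals, CPM exact Poisson intervals, and ratios exact conditional binomial intervals, all at 95%. They cover counting error only and compare these libraries, not the tissues. One count is worth 0.141 CPM in seed coat parenchyma and 0.0694 CPM in whole seed. Before the data were examined, a list of 38 miRNA families in 8 groups, with 48 mature sequences, was fixed from general knowledge. These sequences and those of the proteins were not checked against a database, which bears most on values for exact mature sequences. A tag of 19 to 24 nt belonged to a family if it held mature positions 2 to 17 without mismatch, starting within 2 nt of the expected place. The rule for naming was fixed then too. All families were measured, and the text may name those past the size rule, the 10 most abundant families and tags of each library, and those whose interval holds 1. The other measured members of the lists (miR157, miR160, miR168, miR408 and miR1509) and tasiARF are named outside that rule, to complete each list. The size rule asks for a ratio of at least 2 or at most 0.5, an interval excluding 1, and 100 combined counts.

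No genome was used, so listed mature sequences without a genome match could not be removed, and gene list ratios, feature shares, small RNA per gene, phased loci and embryo and seed coat marker genes were not analysed. Chalcone synthase was instead measured by translation, after the files had been looked at. A tag counted if any frame of either strand encoded 6 consecutive residues (18 nt) of the protein and the tag belonged to no listed family. Each of 6 proteins, written from general knowledge, had 100 shuffled versions as its background. The gene table of assembly Glycine_max_v4.0 served only to count miRNA genes per family.

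The alternatives were other scalings, count minimums, ratios and matching rules, and tags left out for abundance. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, edlib 1.3.9.post1 and matplotlib 3.10.9 were used. The rule was tested on simulated data at the real library totals, with 1000 features. It called 100% of 50 features made 4-fold higher, 96% of 50 made 2.5-fold higher, 100% of 34 at a ratio of 0.25 and 90% of 40 at a ratio of 0.4 that reached the count minimum. It called none of 762 unchanged features, and the intervals held the true ratio in 95.2% of cases. The simulation had counting error only.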

Results

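Small RNAs of soybean (Glycine max, cultivar Asgrow A3237) seeds at early maturation were sequenced from 2 sources. One was the seed coat parenchyma, the tissue of thin-walled cells inside the seed coat, cut out of fixed sections by laser capture microdissection. The other was the whole seed, which includes the seed coat and the embryo. Each group was 1 library, from seeds 5.2 to 8.0 mm long. The seed coat parenchyma library held 7081818 counts in 2899028 distinct sequences (tags), and the whole seed library 14409061 counts in 6827143 tags. With 1 library per group no difference had a replicate check, and no test was run. Values are given with 95% intervals, which cover counting error only, since PCR copies are not independent molecules. A difference was called by size: a ratio of counts per 1000000 library counts (CPM) of at least 2 or at most 0.5, an interval that excluded 1, and at least 100 counts in the 2 libraries together.

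The first comparison asked which size classes of small RNA each source held. In plants, 21-nt and 22-nt RNAs include most microRNAs (miRNAs) and secondary small interfering RNAs, and 24-nt RNAs are mostly those that guide DNA methylation. The 24-nt class was the largest in both libraries, with 52.5% of counts in seed coat parenchyma (Clopper-Pearson interval 52.5% to 52.6%) and 56.3% in whole seed (56.3% to 56.4%). The 21-nt class followed, with 23.4% in seed coat parenchyma (23.4% to 23.4%) and 29.2% in whole seed (29.2% to 29.2%). This difference of -5.77 percentage points was -11.2 over tags with at least 2 counts and -3.17 without the 10 most abundant tags of each library and their 1-mismatch neighbours. Tags of 22 nt held 8.70% of counts in seed coat parenchyma and 6.81% in whole seed, and those of 23 nt held 6.85% and 4.67%. The widest ratios were in the shortest tags. The 18-nt class was 5.27 times as large a share in seed coat parenchyma as in whole seed (1.98% and 0.375%), and the 19-nt class 4.36 times (2.54% and 0.583%).

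Among distinct tags, 62.0% were 24 nt long in seed coat parenchyma and 71.0% in whole seed, and 10.7% and 12.7% were 21 nt long. The order of the 24-nt shares of counts depended on rare tags. Over tags with at least 2 counts, the 24-nt share was 2.06 percentage points higher in seed coat parenchyma, whereas over all tags it was lower (difference of -3.81 points). Tags seen once made up 75.0% of distinct tags in seed coat parenchyma and 84.7% in whole seed, and the whole seed library was 2.03 times as deep.

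**Figure D1:**
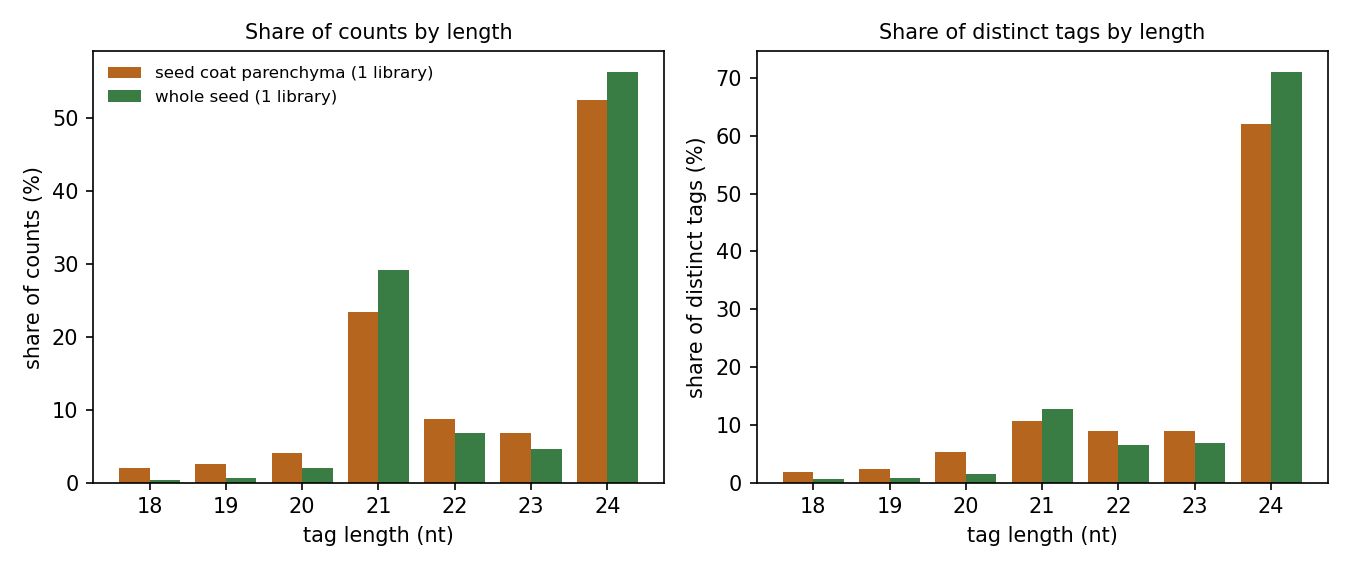
Share of counts (left, %) and of distinct tags (right, %) by tag length in nt, for the seed coat parenchyma library and the whole seed library, with 1 bar per library. The 24-nt class is the tallest in both libraries (52.5% and 56.3% of counts), and the 18-nt and 19-nt classes are larger in seed coat parenchyma.

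The second comparison asked how much of each library belonged to known miRNAs, and which families differed. The 38 families of a list fixed in advance made up 0.906% of counts in seed coat parenchyma (0.899% to 0.913%) and 8.67% in whole seed (8.66% to 8.69%). This share was 9.57-fold lower in seed coat parenchyma (9.49 to 9.64). In the same library, tags of 18 to 20 nt held 8.51% of counts against 3.01% in whole seed, and tags with the 5.8S rRNA start 1.81% against 0.698%. A single family, miR3522, held 70.9% of the family counts in whole seed and 13.5% of those in seed coat parenchyma. Without it the shares were 0.784% and 2.52%. The gap also depended on which tags were counted. The most abundant tag of seed coat parenchyma, GGAATGGGCTGATTGGGAAGC, lay outside the list, but its sequence was within 3 edits of the reverse complement of miR482. Without gaps its best pairing in the list was with miR398, over 14 of 18 bases, and no precursor was used to place it. It held 9.85% of counts there and 5.43% in whole seed, a ratio of 1.81 (1.81 to 1.82). Counting that tag and 2 other abundant tags that pair with a listed family, the shares were 11.5% and 15.3%. That choice was made after the sequences were seen.

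Of the 38 families, 28 reached 100 combined counts, and of these 7 were higher and 13 lower in seed coat parenchyma, with 8 inside the 2-fold bounds. The median log2 ratio was -0.59 over the 27 with counts in both libraries, and -0.72 with miR397, which had 0 counts in seed coat parenchyma, at its bound. Scaled to either median, 9 families were higher and 12 lower. Scaled to family counts, which miR3522 dominates in whole seed, every log2 ratio rose by 3.26, and 20 families were higher and 3 lower.

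Of the 5 families that target disease resistance genes of the NB-LRR class, 3 were higher in seed coat parenchyma, 1 was lower and 1 neither. The largest ratio of any family was that of miR2118, at 340 CPM (327 to 354) against 33.9 CPM (30.9 to 37.0), or 10.04-fold (9.11 to 11.1). Its near relative miR482 was 6.03-fold higher (5.23 to 6.98), on 753 and 254 counts. The far more abundant tag within 3 edits of its reverse complement (697418 and 783048 counts, ratio 1.81) was not counted in it. The miR1510 family was 2.46-fold higher (2.32 to 2.60), but this call was lost under 3 other matching rules: its log2 ratio was -0.21 with 1 mismatch allowed, 0.83 for the exact mature sequence and 0.29 in the listed direction. The listed direction held 48.9% of its counts in seed coat parenchyma and 98.5% in whole seed, so the 0.29 also depends on how tags were written. The miR1510 count also left out a tag that pairs with it over 18 of 19 bases (46280 and 65906 counts, ratio 1.43). Both left-out tags were inside the 2-fold bounds. The miR2109 family had a ratio of 1.04 (0.954 to 1.14). The miR1507 family was 3.47-fold lower (3.05 to 3.95), and more than 2-fold higher when scaled to family counts.

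In the auxin list, miR167, which targets auxin response factor genes, was 3.23-fold higher in seed coat parenchyma (3.15 to 3.32), with 1950 CPM against 603 CPM. Only a minority of its counts were the listed mature sequence itself (412 and 2553 counts), and for that sequence alone the log2 ratio was -1.61. The other measured member, miR160, had a ratio of 1.51 (1.10 to 2.07). miR390, which starts the TAS3 pathway of secondary small RNAs against auxin response factors, was 5.52-fold higher (4.68 to 6.53). The other member of its list, tasiARF, a product of that pathway, had 8 and 38 counts, below the minimum, and a ratio of 0.428 (0.173 to 0.932), which rose above 1 when scaled to family counts.

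The developmental list was mostly lower in seed coat parenchyma, with 6 of its 10 measured families lower, 1 higher and 3 neither. miR172, which targets AP2-type transcription factors, was 24.3-fold lower (21.3 to 27.8), with 32.5 CPM against 789.7 CPM. The listed mature sequence itself had only 6 and 14 counts, too few for a call, with a log2 ratio of -0.20. miR166, which targets class III HD-ZIP leaf polarity genes, was 16.2-fold lower (14.9 to 17.6), with 80.2 CPM against 1299 CPM. Both had ratios below 1 under each scaling tried, but scaled to family counts the log2 ratio of miR166 was -0.76 and its call was lost. miR156, which targets SPL phase-change genes, was 7.96-fold lower (7.06 to 8.99), and miR159, which targets GAMYB-type genes, 5.21-fold lower (5.14 to 5.28). miR319, which targets TCP genes, was 3.55-fold lower (3.35 to 3.76), with a log2 ratio of -4.84 for the exact mature sequence (8 and 467 counts). With 1 mismatch allowed, miR319 had 518 and 7564 counts, fewer than the 1342 and 9681 under the stricter main rule. Under that rule the first matching place in a tag decided, and the listed miR319 sequence matched miR159 there with 1 mismatch. With 1 mismatch allowed, miR159 had 31583 and 334912 counts, against 25548 and 270774 under the main rule. The log2 ratio of miR319 there, -2.84, is therefore no check of this family. That of miR159, -2.38, is no independent check either. How many tags moved between them was not counted. miR169, which targets NF-YA genes, was 2.35-fold lower (1.64 to 3.45). Scaled to family counts, these last 4 families had ratios above 1, and those of miR319 and miR169 passed 2. miR169 also lost its call when scaled to the median or to 21-nt counts. miR394, which targets an F-box gene, was 5.38-fold higher (3.83 to 7.67), on 127 and 48 counts. miR164, miR396 and miR157 had ratios of 1.06, 1.07 and 0.715. With 1 mismatch allowed, miR157 had 2576 and 15040 counts and was called lower, while miR156 had 365 and 5741. The gene table held 0 genes for miR157 and 28 for miR156, so the split of counts between these families is uncertain.

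In the nutrient list, miR395, which responds to sulfate, was 4.04-fold higher in seed coat parenchyma (3.42 to 4.78). miR398 and miR397, which target copper proteins, were lower. miR398 was 9.22-fold lower (6.39 to 13.8), with a log2 ratio of 0.053 when scaled to family counts. miR397 had 0 counts in seed coat parenchyma and 203 in whole seed, which is at least 33.3-fold lower against a floor of 3 counts in the library, while the 95% interval reaches to 26.8-fold lower. Nearly all of its counts were listed as the reverse complement, and in the listed direction alone it made no call. miR408 had a ratio of 0.556 (0.497 to 0.622). Of the small RNA pathway list, miR162, which targets DCL1, was 4.02-fold lower (2.93 to 5.66), and more than 2-fold higher when scaled to family counts, and miR168, which targets AGO1, had a ratio of 1.37 (1.11 to 1.69). No family of the MYB list reached 100 counts.

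Among families with counts in both libraries, the largest difference was in the legume list. miR3522 was 50.4-fold lower in seed coat parenchyma (49.4 to 51.5), with 1220 CPM against 61524 CPM. It stayed lower under each scaling tried, with a log2 ratio of -5.66 here and -2.40 scaled to family counts. Its tag TGAGACCAAATGAGCAGCTGA was the most abundant sequence of the whole seed library, with 5.83% of counts. miR1511 was 4.95-fold lower (4.62 to 5.32) and miR1508 3.67-fold lower (3.51 to 3.84), both with ratios above 1 when scaled to family counts (above 2 for miR1508), and miR1509 had a ratio of 0.665 (0.601 to 0.734). The most abundant families of seed coat parenchyma were miR159, with 3608 CPM, miR167 and miR3522, and those of whole seed were miR3522, miR159, with 18792 CPM, and miR166. Each tag was counted for 1 family only. Closely related families (miR156 and miR157, miR159 and miR319, miR165 and miR166, miR482 and miR2118) have similar sequences, so their separate values are uncertain.

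**Figure D2:**
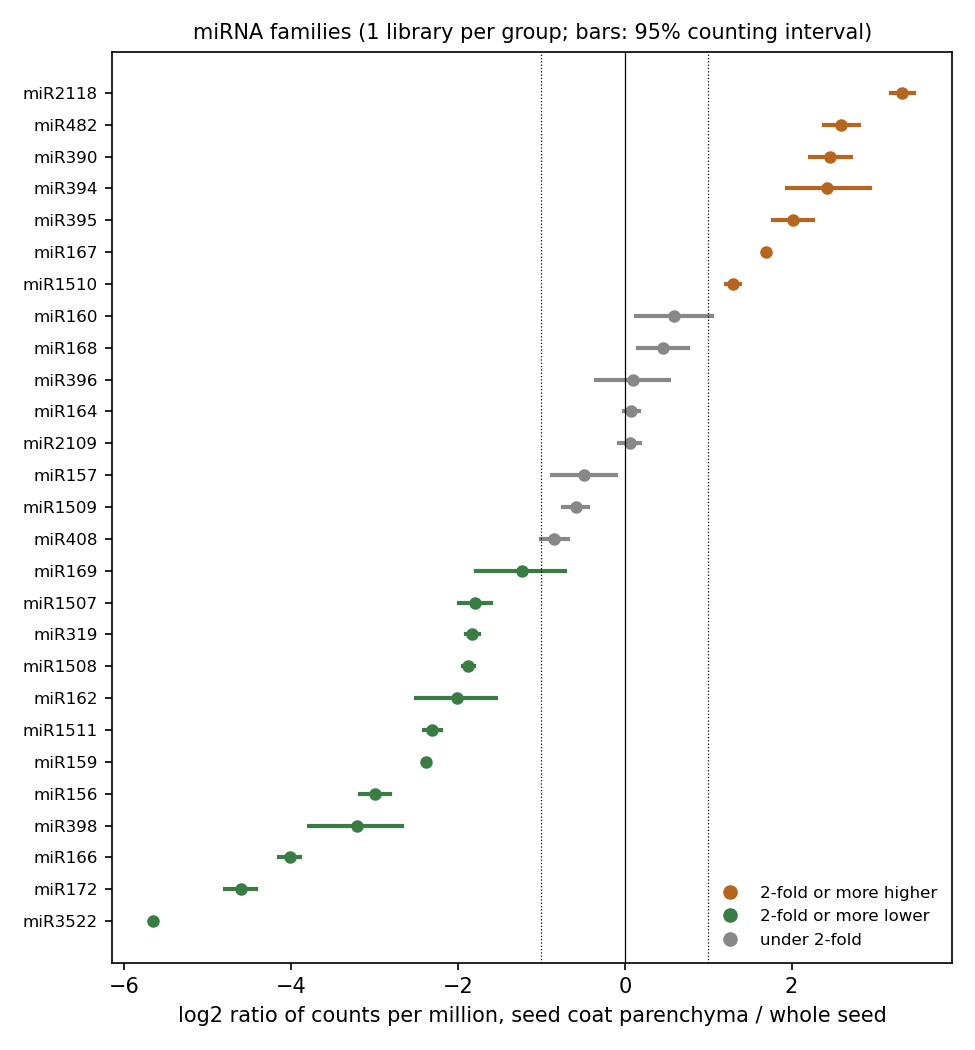
The log2 ratio of CPM, seed coat parenchyma over whole seed, for the miRNA families with at least 100 combined counts, except miR397, which had 0 counts in seed coat parenchyma. Points are single ratios of 1 library to 1 library, bars are 95% counting intervals, and dotted lines mark 2-fold. miR2118 lies highest (10.04-fold higher) and miR3522 lowest (50.4-fold lower); scaled to family counts all points move up by 3.26, and the lower families other than miR3522, miR172 and miR166 then lie above 0.

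The third comparison concerned small RNAs of chalcone synthase, the first enzyme of flavonoid synthesis, whose genes are known to be silenced by small RNAs in yellow soybean seed coats. Tags that encode 6 consecutive residues of a chalcone synthase protein on either strand came to 4875 CPM (4823 to 4926) in seed coat parenchyma and 4214 CPM (4180 to 4247) in whole seed. The ratio was 1.16 (1.14 to 1.17), below the 2-fold bound, but it was 1.74 scaled to the family median and 11.1 scaled to family counts. For 100 shuffled versions of the protein, the median was 83.0 CPM and 82.8 CPM and the highest 1444 CPM and 516.8 CPM. The tags reached 97.1% of the 6-residue windows in seed coat parenchyma and 97.4% in whole seed, against at most 37.6% and 58.0% for the shuffled proteins. The same match to glycinin and Kunitz trypsin inhibitor, seed proteins of the embryo, and to the Rubisco large subunit, actin and ubiquitin gave counts within the range of their shuffled versions in both libraries. Those ranges were wide, so this says little. In seed coat parenchyma the highest shuffled version was at 5280 CPM for glycinin, above chalcone synthase itself, and at 130 to 792 CPM for the others. The Rubisco large subunit had 196 CPM in seed coat parenchyma against a shuffled median of 93.4 CPM, and ubiquitin 34.5 CPM in whole seed against 15.6 CPM.

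The lengths of the chalcone synthase tags differed between the libraries. Tags of 21 nt came to 2408 CPM (2372 to 2445) in seed coat parenchyma and 2819 CPM (2791 to 2846) in whole seed. Tags of 22 nt came to 1265 CPM (1239 to 1291) and 664 CPM (651 to 678), and those of 24 nt to 767 CPM (747 to 788) and 435 CPM (425 to 446). The direction of the total thus rested on tags of other lengths than 21 nt, for which the ratio was 0.854. The members of the chalcone synthase gene family and the strands cannot be told apart by this match, which replaced the planned match to annotated genes after the data were examined.

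**Figure D3:**
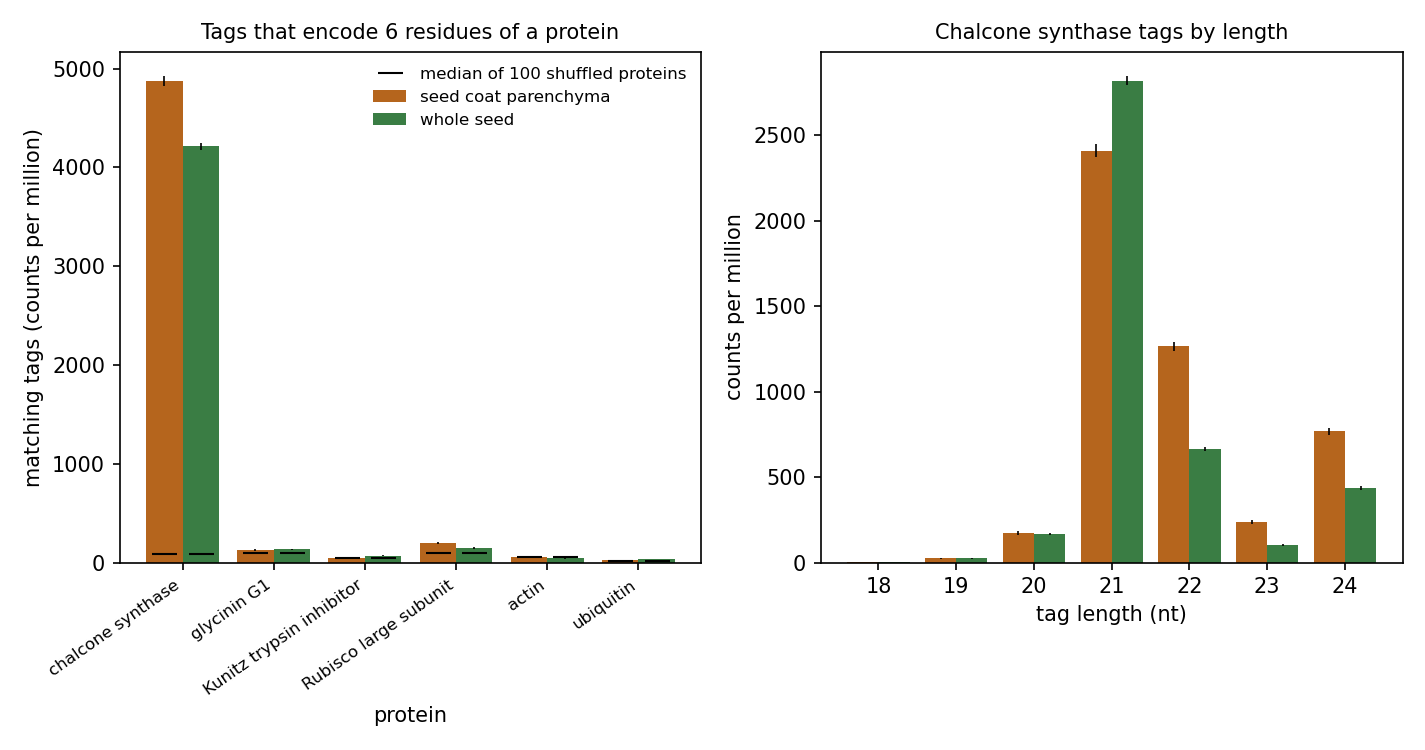
Left, CPM of tags that encode 6 residues of each of 6 proteins, for the seed coat parenchyma and whole seed libraries, with the median of 100 shuffled versions as a black line. Right, CPM of the chalcone synthase tags by length in nt. Error bars are 95% Poisson intervals. Chalcone synthase tags stand at 4875 and 4214 CPM, with 21 nt the most abundant length in both libraries.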

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

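Leaving out a replicate and a paired analysis were both impossible with 1 library per group, and no test was run. The alternatives in the listed direction only, without the most abundant tags and their 1-mismatch neighbours, without miR3522, with the abundant pairing tags, without rRNA tags, the family median with miR397 at its bound, and the chalcone synthase scalings by family counts, by the family median and without abundant tags were chosen after the data were examined. Leaving out rRNA matches removed no tag and says nothing. Alternatives that need a genome were not run.

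The difference in the 21-nt share of counts, -5.77 points, was -11.2 over tags with at least 2 counts, -11.4 over those with at least 5, -3.81 without the 10 most abundant tags of each library and -3.17 without their neighbours too. The 24-nt difference, -3.81 points, became 2.06 and 3.12 over tags with at least 2 and 5 counts, and was -5.86 and -6.47 without the abundant tags. Among distinct tags, the 21-nt difference of -2.03 was -1.80 and -2.41 at those minimums, and the 24-nt difference of -9.06 was -8.53 and -6.00.

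The ratio of the miRNA shares, 0.105, was 0.0709 for exact mature sequences, 0.118 with 1 mismatch, 0.0876 in the listed direction, 0.311 without miR3522 and 0.752 with the 3 abundant pairing tags. The 7 higher and 13 lower families became 20 and 3 scaled to family counts, and 4 higher at a combined count of at least 1000. With 1 mismatch they were 6 and 15, with miR157 then among the lower. Scaled to family counts the log2 ratios of called families turned to 0.27 for miR156, 0.88 for miR159, 2.02 for miR169, 1.43 for miR319, 0.053 for miR398, 1.25 for miR162, 1.46 for miR1507, 1.38 for miR1508 and 0.95 for miR1511, by construction, since the scaling added 3.26. The log2 ratio of miR167 was -1.61 for the exact mature sequence and that of miR1510 -0.21 with 1 mismatch, and the cause was not tested. These were 11 of 171 values of called families under other settings. Another 60 kept their direction but moved by over 1.5 times, most by a scaling. Of these, exact mature sequences gave -0.20 for miR172 (call lost), -4.84 for miR319, -5.00 for miR166, -2.59 for miR1508 and -1.68 for miR1511. With 1 mismatch, miR169 had -2.38 and miR319 -2.84, the latter on fewer counts and so no check. The listed direction gave 0.29 for miR1510 (call lost), 6.67 for miR482, -5.44 for miR156, -7.06 for miR398 and -3.17 for miR166. These values also depend on the direction in which each library's tags were written. miR1510 also lost its call for the exact sequence (0.83), and miR166 scaled to family counts (-0.76). miR169 lost its call scaled to 21-nt counts (-0.92) or to the median (-0.64, and -0.52 with miR397 at its bound).

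The chalcone synthase ratio of 1.16 was 0.854 for 21 nt, 1.44 scaled to 21-nt counts, 11.1 scaled to family counts, 1.74 by the family median and 1.12 without abundant tags. Families below 100 counts, 10 of 38, were not called, and 4 of them had 0 counts in both libraries. Whether depth or the unchecked listed sequences account for this was not tested.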

Other observations

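Many single tags differed between the libraries. Of 7498 tags with at least 100 combined counts, 2382 were 2-fold or more higher in seed coat parenchyma and 2219 lower. Among 21-nt tags, 436 were higher and 837 lower of 1714, and among 24-nt tags 1189 were higher and 816 lower of 3951. Of the 92 tags of 18 nt, 67 were higher. Counting a sequence and its reverse complement as 1, 498113 of 9220064 sequences were found in both libraries, and these held 54.3% of counts in seed coat parenchyma and 45.1% in whole seed.

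Abundant tags outside the family list included AGGGATAGGTAAAACAATGAC, which paired with miR1510 over 18 of 19 bases and held 0.654% of counts in seed coat parenchyma and 0.457% in whole seed. GGAATGTTGTCTGGCTCGAGG, which paired with miR166 over 16 of 19 bases, held 0.0738% and 0.711%, a ratio of 0.104 (0.101 to 0.107). The unassigned 22-nt tag ATGCTCTAAGAATGTTCAGTTA had 2240 and 16845 counts. Chalcone synthase tags were unevenly shared; the following pair was chosen after their values were seen. TGGCTGAGAACAACAAGGGTG had 1894 counts in seed coat parenchyma and 17 in whole seed, and GCCAGCCAAAGTCAAAGATTA had 31 and 2118.

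In the 3 patterns weighed below, the tests of tag direction, of the 5.8S rRNA start, of general mRNA breakdown and of random breakage were chosen after the results were seen. The tests of rRNA matches, of the 21-nt share of chalcone synthase tags, of shuffled proteins and of scaling were fixed before. The match by translation and 3 chalcone synthase scalings (by family counts, by the family median and without abundant tags) were chosen after the data were examined.

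Known miRNAs were listed as their reverse complement in 20 of 68 detections. Antisense RNA as the whole cause would leave both directions in a library, and 0% of the detections had both. Of all tags, however, only 0.177% in seed coat parenchyma and 0.159% in whole seed had their reverse complement listed too. With so few tags of any kind listed in both directions, this test cannot decide about antisense RNA. Tags may have been written in the direction of their genome match. First-base shares of distinct 24-nt tags would then mirror the last bases, and they differed from the complement of the last-base shares by at most 1.31 percentage points. Of the 3 measured families with 1 gene in the gene table, however, only 2 had at least 95% of counts in the same direction in both libraries, so the explanation stays open, and apart from antisense RNA no biological explanation was tested.

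Tags of 18 to 20 nt held 8.51% of counts in seed coat parenchyma and 3.01% in whole seed. Fragments of rRNA are a candidate explanation. Tags that lie wholly within the 3 rRNA stretches held 0% of the difference because there were no such tags in either library, so that test was void. Fragments of the 5.8S rRNA start, tags that overlap the start of the 5.8S stretch, held 16.3% of the difference (29.6% at 18 nt, 34.8% at 19 nt and -13.2% at 20 nt) and leave most of it unassigned. Steps of 1 nt changed them sharply: ACAATGACTCTCGGCAACG had 46225 counts in seed coat parenchyma and 7 in whole seed, and ACAATGACTCTCGGCAACGG had 2 and 44048. RNA breakdown in fixed tissue, the library preparation and the compartment itself stay open and cannot be told apart with 1 library each.

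Chalcone synthase tags were 1.16 times as frequent in seed coat parenchyma, short of the 2-fold bound, but 11.1 times scaled to family counts and 0.854 times for 21-nt tags alone, so no difference between the tissues is shown. Against chance peptide matches as the source of the level itself, 0 of 100 shuffled proteins reached it. General breakdown of abundant mRNAs would also bring in fragments of other proteins. Of 5 control proteins, 0 lay above every one of its shuffled versions. For glycinin in seed coat parenchyma this was void, because its highest shuffled version, at 5280 CPM, exceeded chalcone synthase itself. All 5 controls lay at 24.7 to 196 CPM there, against 4875 CPM for chalcone synthase. In whole seed they lay at 34.5 to 148 CPM, against 4214 CPM. Tags of these 5 proteins thus did not reach its level. The amounts of the mRNAs were not measured, so the test does not decide about general breakdown. Fragments of broken mRNA of chalcone synthase alone were not decided by the test set in advance, because 21-nt tags were 49.4% of these counts in seed coat parenchyma, just under 50%, against 66.9% in whole seed, and the rRNA tags meant for comparison were missing. Random breakage of chalcone synthase mRNA would leave no sharp peak, and 21-nt counts were at least 10.2 times the 20-nt and 23-nt counts in both libraries, though only 1.90 times (seed coat parenchyma) and 4.24 times (whole seed) the 22-nt counts. Over all tags, counts also rose from 20 to 21 nt, from 282675 to 1657905 in seed coat parenchyma and from 295809 to 4203976 in whole seed. That step is therefore not particular to chalcone synthase. From 22 to 23 nt, all tags went from 615803 to 485345 and from 981419 to 672441. Chalcone synthase tags went from 8956 to 1667 and from 9572 to 1460. Only this step goes against random breakage, in a test chosen after the results were seen, and it leaves breakage at set lengths open. The lowest ratio under other scalings was 1.12 and none fell to 1. The scalings tried multiply any ratio by at least 0.971, so none of them could have brought 1.16 to 1. Not every scaling kept the ratio at 2 or above, the bound set in advance against scaling. The test therefore does not decide about library scaling. Small interfering RNAs against chalcone synthase in the seed coat remain an untested biological explanation.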
